A study of Mus musculus with 22 samples.

How the data were processed

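Drop-seq, in which single cells are caught in droplets with barcoded beads and their RNA is counted by molecular identifiers, was run on the hippocampus of 22 mice. The labels place the mice in 6 groups: 5 old wild-type (WT), 4 old rTg4510, 3 old P301L, 3 old rTta, 4 young WT and 3 young rTg4510. The rTg4510 line carries a human tau cDNA with the P301L mutation under a tetracycline operator, switched on by a tetracycline transactivator (tTA) under the Camk2a promoter. By their names, the P301L and rTta animals carry the tau responder alone and the transactivator alone, which the labels do not spell out. Old WT animals were 32 to 40 weeks old, old rTg4510 32 to 38, rTta 33 and P301L 41 to 48, and young animals were 4 to 6 weeks old per the labels, whereas the series summary gives a lower range for the young animals. All animals share 1 strain label, a mixed background.

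The authors deposited 1 table of counts, whole numbers for 13685 genes in 30500 cell barcodes. The deposited notes state demultiplexing with bcl2fastq 2.18.0.12 and alignment with STAR, given as version 2.2, to the mouse genome build mm10. They state neither the counting tool, nor the annotation, nor any filter on genes or barcodes, nor whether the counts are of distinct molecular identifiers. No value in the table was other than a whole number, and every column carried the number of 1 animal. The zeros showed that the table had been merged from 2 parts: 12614 genes had a count in each of the 22 animals, 270 were at 0 in all 6 P301L and rTta animals and counted in each of the other 16, and 801 showed the opposite pattern. Comparisons of P301L or rTta with WT or rTg4510 therefore also compared the parts. Only genes counted in all 22 animals entered the main fits of every comparison, also of those among WT and rTg4510 animals. The 270 genes were added only in an alternative fit of those 16 animals. No gene with a mitochondrial prefix was in the table.

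The total count per animal ran from 780831 to 6039656. Barcodes with at least 300 counts were kept, 27198 in all, with median counts per kept barcode between 638 and 2021 among the animals. This minimum was chosen after the distribution of counts had been seen. Ratios for genes with few counts carry an exact 95% interval that covers counting error alone, and a group at 0 was set to 3 counts over the group.

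The analysis plan had assumed deposited cell types, but the files held none, so the cells were clustered. With scanpy 1.11.5 (anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15), counts were scaled to 10000 per cell and log-transformed. Then 2000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 30 clusters. A cluster was named from marker lists fixed before the data were examined, when at least 3 markers of a class stood at least 2-fold above the other clusters after 20 CPM (counts scaled to the total of a sample) had been added. The details of this rule, including the merging of 4 clusters of excitatory neurons, were set after the clusters had been seen. In all, 24329 cells were named and 2869 (10.5%) were left unnamed. No doublet caller was run, and 2120 named cells held more marker counts of another class than of their own. Classes are named here for the markers they carried.

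Counts were summed per animal within each class, for animals with at least 20 cells of the class. Groups were compared with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test with robust dispersion) in R 4.3.3, with 1 fit per class over all 6 groups. Adjusted p values are Benjamini-Hochberg values within a class, with a threshold of 0.05. A class was tested where each compared group kept at least 2 animals. Log2 changes are given with their standard error (SE), and CPM values as the mean over animals with its standard deviation (SD). Of the comparisons, 8 were planned and that of old P301L with old rTta was added after the 2 parts of the table had been seen. Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over all lists and classes of a comparison, 219 tests in the main one. Shares of cells were compared with exact two-sided permutation tests over animals. On simulated data with the observed counts and group sizes of the main comparison, a log2 change of 2 was called for 94.9% of changed genes in microglia, and a log2 change of 1 for 28.0% there, 38.3% in astrocytes, 52.0% in oligodendrocytes and 66.3% in excitatory neurons. The simulated calls held 2 to 8 false ones per class. The simulated spread of a gene followed its expression level alone, and no variation was shared among the genes of an animal. These rates may therefore be better than those in the real data.

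Genes named in the text follow a rule fixed before the data were examined. In the classes with most called genes (3 in the main comparison, 2 in the others), it takes the 4 (elsewhere 3) largest rises and falls among called genes with at least 50 CPM in the higher group. Added to these are the called members with the smallest adjusted p of each list with 3 or more calls, and the genes tied to the transgenes. The last are Mapt and Prnp, which the tau cDNA and its vector can add reads to, Camk2a, whose promoter drives tTA, Fgf14 at the tau insertion, and Wdr60, Esyt2, Ncapg2 and Ptprn2 at the tTA insertion. Sex-linked genes, ribosomal protein genes and predicted models were left out of the rule. Positions come from GENCODE vM21 on mm10, where 151 of 153 named genes had 1 position.

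Alternatives tried were RLE factors, DESeq2 1.42.0, no low-count filter, at least 50 cells, fits of the compared groups alone, a term for the ranges of animal numbers, cells above the lower quartile of counts, and the omission of each animal. Added after the data had been seen were the removal of cells with mixed markers, of single clusters, and a fit of the 16 WT and rTg4510 animals with their own genes. The animal numbers fall into ranges, 2 for old WT and rTg4510 animals and 2 for young ones, which are treated as possible batches. P301L and rTta each form a range of their own. No date or batch is given in the labels.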

Results

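Single-cell counts from the hippocampus of 22 mice were compared between tau transgenic rTg4510 animals and wild-type (WT) littermates at an old and a young age, and with old animals of the P301L and rTta groups. The groups held 5 old WT, 4 old rTg4510, 3 old P301L, 3 old rTta, 4 young WT and 3 young rTg4510 animals. Total counts per animal ran from 780831 to 6039656, and 27198 cells were kept. Excitatory neurons made up 30.7% ± 4.42 (SD, n = 5) of the cells of old WT animals, oligodendrocytes 16.1% ± 7.46, astrocytes 13.4% ± 1.41, microglia 7.64% ± 2.34 and endothelial cells 5.99% ± 1.65. Every animal had Xist counts, between 560 and 1251 CPM (counts scaled to the total of a sample), as female animals have.

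The transgene was read first, as a check of the labels. Mapt, which encodes tau (chromosome 11, 104231390 to 104332090 on mm10), stood in excitatory neurons at 1728 ± 323 CPM (SD, n = 4) in old rTg4510 and 1610 ± 236 (n = 3) in young rTg4510 animals. It stood at 527 ± 58.8 (n = 5) in old WT, 518 ± 44.3 (n = 4) in young WT, 534 ± 47.3 (n = 3) in P301L and 599 ± 80.8 (n = 3) in rTta animals. Prnp, the prion protein gene whose vector carries the tau cDNA (chromosome 2, 131909928 to 131938429), was at 3239 ± 130 CPM in old rTg4510 and 1435 ± 442 in old WT animals, a log2 change of 1.18 ± 0.19 (SE, edgeR adjusted p = 0.0011). Mapt and Prnp counts can hold reads from the transgene, so they do not measure the mouse genes alone. Wdr60 (chromosome 12, 116206262 to 116263022) is 1 of the genes at the tTA insertion. Over all cells it was lower in each group that carries tTA by its line or name. It stood at 64.7 CPM in old rTg4510, 50.6 in young rTg4510 and 40.3 in rTta, against 128 in old WT, 150 in young WT and 94.9 in P301L. The 3 P301L animals stood at 140.5, 84.6 and 59.5 CPM, and the lowest of these, replicate 3, lay within the old rTg4510 animals (57 to 70.1). Replicate 3 also stood between the rTta and WT animals for Rpl3, Rps2, Rps18 and Pttg1. For Scg5 (255.9 CPM, 203.3 to 256.8 in rTta) it stood within the rTta animals, and for Gabra2 (63.6, 69.5 to 85.1) below them. The other P301L animals stood at 347.8 and 469.7 CPM of Scg5 and 129.4 and 195.3 of Gabra2. Replicate 3 stood with the other P301L animals and away from rTta for Hddc3 (55.3 CPM, 8 to 13.2 in rTta), Wdfy1 (60.9, 18.5 to 21.4), Fcho1 (67.8, 15.9 to 26.9) and Eya2 (23.5, 1 to 2). Over all cells the fall of Wdr60 passed the test between rTta and WT (log2 change -1.66 ± 0.29, adjusted p = 0.012), and not between old rTg4510 and WT (-0.98 ± 0.25, adjusted p = 0.13). Esyt2, at the same insertion, was at 28.3 CPM in old rTg4510, 28.0 in rTta and 50.7 in old WT. Its fall passed the test between rTg4510 and P301L (-1.07 ± 0.21, adjusted p = 0.020). Fgf14, at the tau insertion, averaged 9.56 CPM in old rTg4510 and 10.6 in P301L, against 17.8 in old WT and 21.1 in rTta, with no fall past the test.

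**Figure D1:**
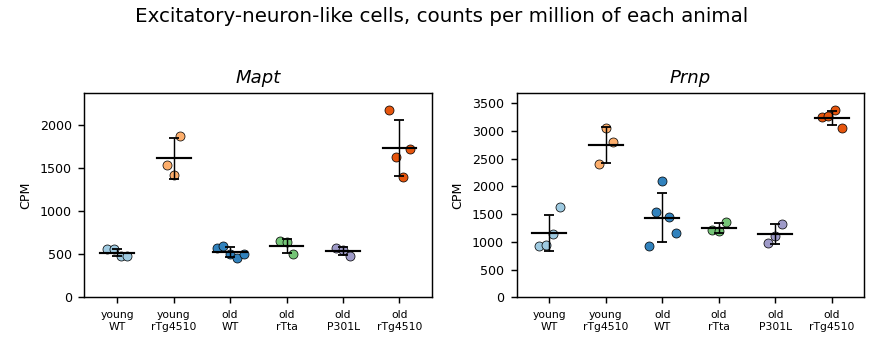
CPM of Mapt and Prnp in excitatory neurons of each animal (points), with the group mean (bar) and SD (whisker); the vertical axes start at 0. The rTg4510 animals of both ages lie above all other animals for both genes.

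The comparison of old rTg4510 with old WT animals asks how cells differ in animals with advanced tau pathology. Microglia changed most: 123 genes were higher and 25 lower, of 4392 tested. The genes that rose included a set known from microglia near damaged neurons and plaques. Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188), rose from 5214 ± 3087 CPM (SD, n = 5) to 48810 ± 19000 (n = 4), a log2 change of 3.22 ± 0.42 (SE, adjusted p = 8.3e-06). Lpl, a lipase that frees fatty acids from lipoproteins, rose from 50.8 ± 22.9 to 491 ± 13.2 (3.27 ± 0.41, adjusted p = 2.2e-06). Of the 22 measured genes of the list of disease-associated microglia, 20 rose over all genes tested and 22 adjusted over the list alone (camera adjusted p = 1.3e-52; adjusted p = 0.0016 with an estimated correlation).

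Other gene groups rose in the same microglia. Of 29 lysosomal genes 15 rose (20 adjusted over the list alone; adjusted p = 0.023 with an estimated correlation), among them Cd63, a tetraspanin of late endosomes (2.56 ± 0.33), the protease Ctsb (1.89 ± 0.28), the glycosidase Gusb (1.76 ± 0.30), Npc2, which binds cholesterol in the lysosome (1.62 ± 0.26), and the protease Ctss (1.24 ± 0.29). The antigen presentation list rose at 6 of 10 genes (6 adjusted over the list alone; adjusted p = 0.041 with an estimated correlation), with H2-D1 at 2.39 ± 0.37, H2-K1 at 1.89 ± 0.31, B2m at 1.84 ± 0.32, and the immunoproteasome subunit Psmb8 at 1.23 ± 0.28. H2-D1 and H2-K1 are near-identical copies, so the split of counts between them is uncertain. Class II genes rose too: Cd74, the invariant chain, went from 41.7 ± 31.6 to 668 ± 532 CPM (4.07 ± 0.98, adjusted p = 0.026), H2-Ab1 rose by 4.03 ± 0.98, and H2-DMa had 157 counts against 3, a ratio of 18.5 (95% counting interval 6.20 to 90.4). Lgals3, a galectin, was at 0 in all 5 WT animals and at 109 ± 20.8 CPM in rTg4510, at least 15.3-fold higher. Complement genes rose at 5 of 8 members (5 adjusted over the list alone), with C1qa, C1qb and C1qc at 1.19, 1.13 and 1.09 and the receptor gene C3ar1 at 1.70 ± 0.30, although the list's call was lost with an estimated correlation (adjusted p = 0.21 with an estimated correlation). The calls of C1qa, C1qb and C1qc were lost in 10, 9 and 12 of 20 alternatives, with an adjusted p of up to 0.39. Of 7 interferon response genes 2 rose (5 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). The 5 of 11 reactive astrocyte genes and 5 of 8 genes of disease-associated oligodendrocytes that rose in microglia (adjusted p = 0.0051 and 0.024 with an estimated correlation) belong to lists that share members such as Apoe, Ctsb, B2m, H2-D1, H2-K1 and Cd63 with the lists above.

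The largest falls in microglia, among genes with at least 50 CPM in WT, were those of Gimap6, an immune GTPase gene (-2.81 ± 0.71), Spry1, an inhibitor of growth factor signals (-2.27 ± 0.46), the ephrin receptor gene Epha2 (-2.26 ± 0.57) and Slc2a5, the fructose transporter that marks resting microglia (208 ± 91.5 to 45.7 ± 19.9 CPM, -2.24 ± 0.37, adjusted p = 7.2e-05). Slc2a5 was the only called member of the 20 homeostatic microglia genes, whose median log2 change was -0.30 (1 adjusted over the list alone; camera adjusted p = 0.0028; adjusted p = 0.55 with an estimated correlation). Of 11 heat shock genes 1 fell (5 adjusted over the list alone; adjusted p = 0.099 with an estimated correlation). Markers of neurons in the microglia droplets had a median log2 change of -0.54 (camera adjusted p = 0.051) and markers of astrocytes of 0.04.

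**Figure D2:**
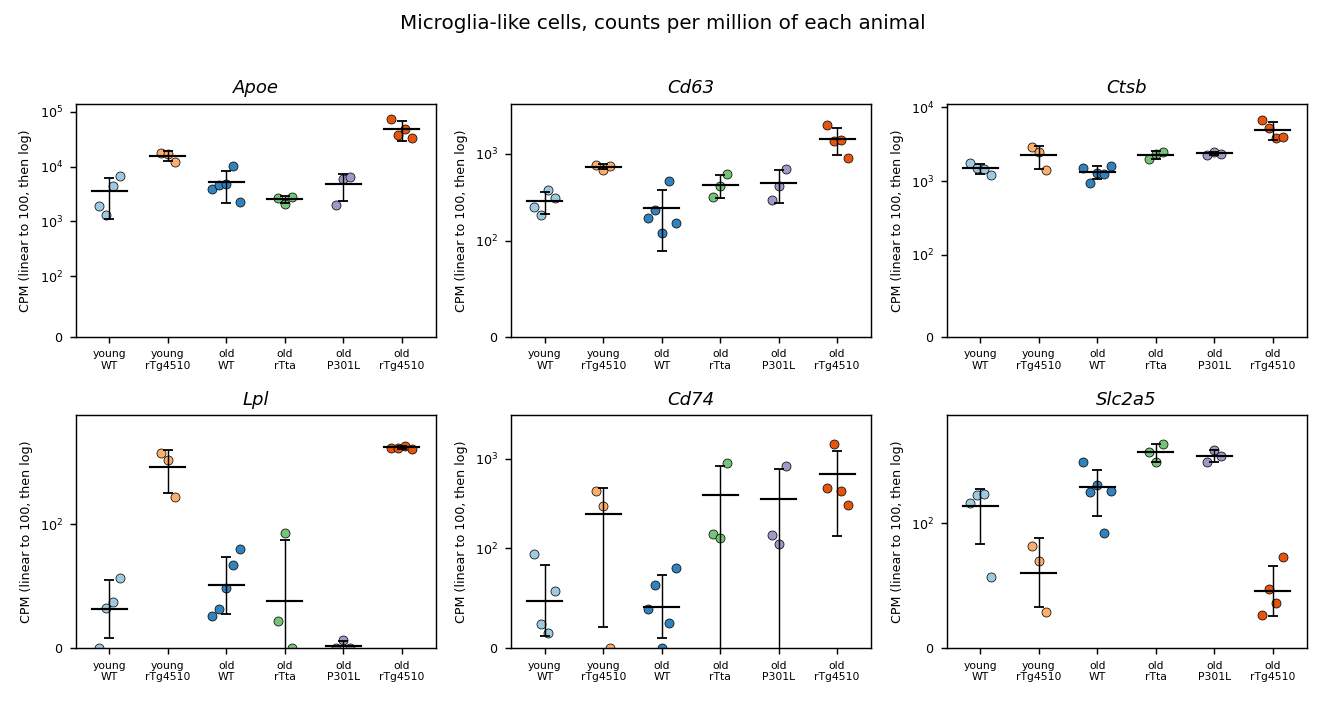
CPM of 6 genes in microglia of each animal (points), with the group mean (bar) and SD (whisker, drawn down to 0 at most); the axis is linear from 0 to 100 and logarithmic above. Apoe, Lpl, Cd63 and Ctsb are highest and Slc2a5 lowest in old rTg4510 animals, and Cd74 spreads widely within groups.

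In astrocytes of old rTg4510 animals 25 genes were higher and 3 lower. These 28 calls fell to 7, 18, 12 and 17 without old WT replicate 1, 3, 4 or 5, to 8 and 4 without old rTg4510 replicate 1 or 3, and to 16 in cells above the lower quartile of counts. They rose to 43 with a term for the ranges of animal numbers and 60 with no low-count filter. Gfap stayed past the threshold in 11 of 18 alternatives and Serpina3n in 5 of 18. Gfap, the intermediate filament gene that marks reactive astrocytes (chromosome 11, 102887336 to 102900912), rose from 452 ± 195 CPM (SD, n = 5) to 2921 ± 1227 (n = 4), a log2 change of 2.66 ± 0.53 (SE, adjusted p = 0.031). Of 12 reactive astrocyte genes 5 rose (11 adjusted over the list alone; adjusted p = 0.015 with an estimated correlation), including the lipid receptor gene S1pr3 (3.98 ± 0.89) and the protease inhibitor gene Serpina3n (2.24 ± 0.49). Other large rises were Aebp1 (2.82 ± 0.61) and the retinoic acid enzyme gene Aldh1a1 (2.48 ± 0.48). Of 4 antigen presentation genes 3 rose (adjusted p = 0.0016 with an estimated correlation): H2-K1 at 1.45 ± 0.26, H2-D1 at 1.43 ± 0.29 and B2m at 1.26 ± 0.28. The falls were those of Igfbp2, an insulin-like growth factor binding protein gene (-1.16 ± 0.26), the calcineurin subunit gene Ppp3r1 (-1.11 ± 0.27) and the neuronal gene Ncdn (-1.09 ± 0.27). The calls of Ncdn and Ppp3r1 were lost in 12 and 9 of 18 alternatives and that of S1pr3 in 8 of 14. Of 15 cholesterol synthesis genes none was called by edgeR, while 14 had negative log2 changes with a median of -0.58 (camera adjusted p = 4.6e-05; adjusted p = 0.099 with an estimated correlation). Markers of microglia in the astrocyte droplets had a median log2 change of 1.08, with 1 of 6 called (4 adjusted over the list alone; adjusted p = 0.099 with an estimated correlation).

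In excitatory neurons of old rTg4510 animals 11 genes were higher and 15 lower. These 26 calls fell to 14 and 16 without old WT replicate 1 or 5 and to 12, 12 and 17 without old rTg4510 replicate 1, 2 or 4. They rose to 48 with DESeq2, 46 with a term for the ranges of animal numbers and 91 in cluster 2 alone. Beside Mapt (log2 change 1.71 ± 0.16, SE, adjusted p = 1.7e-08) and Prnp, the carbonic anhydrase gene Car4 rose from a mean of 54.8 CPM (n = 5) to 276 (n = 4), a change of 2.36 ± 0.29 (adjusted p = 2.8e-05). The protease gene Prss23 (1.81 ± 0.37) and the B cell linker gene Blnk (1.80 ± 0.37) also rose. Among genes with at least 50 CPM in WT the chemokine gene Cxcl12 fell most, from 86.7 ± 32.2 to 13.8 ± 6.24 CPM (-2.61 ± 0.31, adjusted p = 5.4e-06), followed by Mfge8, a bridging protein gene of phagocytosis (-2.25 ± 0.38), the calcium sensor gene of vesicle release Doc2b (-2.03 ± 0.36) and the neuropeptide Y receptor gene Npy2r (-1.80 ± 0.29). Markers of other cells were lower in the same droplets: of 18 homeostatic astrocyte genes, which include Mfge8, 15 had negative log2 changes, with a median of -0.66 (1 called, 2 adjusted over the list alone; camera adjusted p = 2.4e-05; adjusted p = 0.34 with an estimated correlation). Of oligodendrocyte markers 4 of 7 fell when adjusted over the list alone (adjusted p = 0.16 with an estimated correlation), endothelial markers had a median log2 change of -1.42 (adjusted p = 0.12 with an estimated correlation), and 7 of 14 myelin genes fell when adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). Clusters of low counts made up different parts of the class: cluster 4 held 40.6% of excitatory neurons in old WT and 19.3% in old rTg4510 animals, but 14.3% and 4.04% of the counts. Without cluster 4 the class gave 23 calls, and 18 of the 26 were still called, with 0 of opposite sign. Cluster 13, of higher counts, held 104 of 1414 excitatory neurons in old WT and 289 of 1225 in old rTg4510 animals. It was not removed by itself. In cluster 2 alone, 16 of the 21 calls that could be tested were still called, and 1 had the opposite sign. The 3 measured genes at the tTA insertion fell when adjusted over the list alone and not over all genes (adjusted p = 0.029 with an estimated correlation). Interneurons gave 2 calls, Mapt (1.31 ± 0.24) and Prnp (1.70 ± 0.26).

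Over all 9 classes the comparison gave 215 calls in 44011 gene and class pairs, 169 higher and 46 lower, with 3398 pairs at an unadjusted p under 0.05. The remaining calls were 10 in oligodendrocytes and 1 in cluster 15. Cluster 15 was named neurons from the list of neuron markers, and Nxph3, Hs3st4, Rprm and Nr4a2 were among its leading genes. Dynll1, named after its values were seen, fell there by 1.36. Endothelial cells, mural cells and oligodendrocyte precursors had 0 calls by edgeR, with 154, 165 and 236 genes at an unadjusted p under 0.05, and 0, 0 and 0 calls by DESeq2. All 48 pairs of a named gene and class had the same direction in both ranges of animal numbers. The pairs were picked from calls in a fit of these same animals, which favours such agreement. It is therefore no independent test of an effect of the ranges. The count fell to 125 without old WT replicate 1, to 106 without old rTg4510 replicate 1 and to 129 without old rTg4510 replicate 2. It was 336 with no low-count filter and 109 with microglia cluster 12 alone. The 148 calls in microglia became 89 without old WT replicate 1, 83, 86 and 229 without old rTg4510 replicate 1, 2 or 3, 96 with only the groups compared and 42 in cluster 12 alone. They were 108 in cluster 6 alone. This cluster made up 10.9% of the cells of old rTg4510 and 3.47% of those of old WT animals (exact permutation p = 0.032, unadjusted, tested after the clusters had been seen).

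Cell shares differed less clearly. Excitatory neurons made up 30.7% ± 4.42 (SD, n = 5) of the cells of old WT and 22.2% ± 2.53 (n = 4) of those of old rTg4510 animals (exact permutation p = 0.016, adjusted p = 0.19). Microglia made up 7.64% ± 2.34 and 16.6% ± 7.27 (exact permutation p = 0.048, adjusted p = 0.29). None of the 12 shares passed after adjustment, and the smallest p this design can give is 0.0079. Choroid plexus cells made up 34.0% of old rTg4510 replicate 3 and 0% of the other old rTg4510 animals, which lowers the other shares of replicate 3. Shares outside choroid plexus cells were not compared. With each animal left out in turn, the difference in excitatory neurons ran from -9.81 to -6.78 percentage points. Shares after tissue dissociation do not count cells in the tissue.

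The comparison of young rTg4510 with young WT animals asks what differs before pathology has advanced. Each young rTg4510 animal was 1 week younger than the WT animals of its range of animal numbers, 4 against 5 weeks or 5 against 6. Within a range genotype and age therefore cannot be told apart. Both genotypes hold animals of 5 weeks, but these come from different ranges. Excitatory neurons gave 15 of the 19 calls, 7 higher and 8 lower. Mapt rose there by 1.64 ± 0.18 (SE, adjusted p = 9.1e-07), Prnp by 1.25 ± 0.22, and Car4 from 62.4 ± 15.2 CPM (SD, n = 4) to 215 ± 51.1 (n = 3), a log2 change of 1.80 ± 0.30 (adjusted p = 0.0077). The falls included the cation channel gene Trpc6 (-2.39 ± 0.49), the exchange factor gene Net1 (-1.91 ± 0.36) and Npy2r (-1.82 ± 0.33). Wdr60 (-1.47 ± 0.30) and Ptprn2 (-0.99 ± 0.20), both at the tTA insertion, fell as well, 2 of 3 measured genes of that list (adjusted p = 0.021 with an estimated correlation). The calls of Trpc6, Ptprn2 and Wdr60 were lost in 7, 6 and 5 of 18 alternatives, and in excitatory cluster 2 alone Ptprn2 had a log2 change of -0.03 (adjusted p = 0.99). The mix of clusters in this class differed: cluster 4 held 5.66% of excitatory neurons in young WT and 22.3% in young rTg4510 animals, and cluster 2 held 773 of 1572 and 204 of 809. Without cluster 4 the comparison gave 16 calls. Markers of other cells were higher in the same droplets. All 9 astrocyte markers had positive changes, with a median of 1.03 (0 adjusted over the list alone; camera adjusted p = 5.8e-06; adjusted p = 0.29 with an estimated correlation). So did 8 of 8 microglia markers, with a median of 0.71, and 7 of 7 oligodendrocyte markers, with 0.50 (0 and 0 adjusted over the list alone; adjusted p = 0.33 and 0.44 with an estimated correlation). Mapt and Prnp rose in interneurons (1.37 ± 0.25 and 1.64 ± 0.26), and Mapt in the neurons of cluster 15 (1.57 ± 0.27).

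Microglia of young rTg4510 animals had 1 call, Lpl, which is named after its values were seen: it rose from 31.8 ± 23.7 CPM (SD, n = 4) to 330.3 ± 138 (n = 3), a log2 change of 3.35 ± 0.50 (SE, adjusted p = 0.00014). Apoe in the same cells averaged 3609 and 15760 CPM and did not pass the test (2.13 ± 0.46, adjusted p = 0.10). Markers of other cells were higher in these droplets: neuron markers had a median log2 change of 0.96, with 10 of 11 positive (4 adjusted over the list alone; camera adjusted p = 6.5e-06; adjusted p = 0.24 with an estimated correlation). The median was 0.81 for oligodendrocyte markers and 0.61 for astrocyte markers (adjusted p = 0.26 and 0.41 with an estimated correlation). All 9 microglia markers had negative changes (3 adjusted over the list alone; adjusted p = 0.41 with an estimated correlation). In all, young rTg4510 vs young WT gave 2844 pairs at an unadjusted p under 0.05. All 11 named pairs had the same direction in both ranges of animal numbers, but they too were picked from calls in a fit of these same animals. The count of 19 fell to 11, 9, 12 and 12 without young WT replicate 1 or 2 or young rTg4510 replicate 2 or 3, and rose to 34 without young WT replicate 4 and 42 without young rTg4510 replicate 1. DESeq2 called 42, no low-count filter gave 51 and excitatory cluster 2 alone 42.

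The interaction of genotype and age tested whether the rTg4510 difference itself changed with age. Since the young rTg4510 animals were 1 week younger than the young WT animals of their ranges, age within the young groups is part of it. It gave 1 call in edgeR, with 2555 pairs at an unadjusted p under 0.05, and 19 in DESeq2. Sepw1, a selenoprotein gene, stood in microglia at 582 ± 206 CPM (SD, n = 5) in old WT and 261 ± 64.7 (n = 4) in old rTg4510, and at 240 ± 89.5 (n = 4) in young WT and 588 ± 76.8 (n = 3) in young rTg4510 animals (log2 interaction -2.39 ± 0.46, SE, adjusted p = 0.023). None of the 22 disease-associated microglia genes was called by edgeR, while 13 passed adjusted over the list alone (camera adjusted p = 6.7e-09; adjusted p = 0.20 with an estimated correlation). For the 29 lysosomal genes the count was 0, with 9 adjusted over the list alone (adjusted p = 0.20 with an estimated correlation). Neuron markers in the microglia droplets shifted with age too, with a median log2 change of -0.54 between old and 0.96 between young rTg4510 and WT animals and 7 of 11 passing the interaction test adjusted over the list alone (adjusted p = 0.20 with an estimated correlation). The median of all genes in that fit was 0.11. Sepw1 was among the leading genes of excitatory cluster 4, so a change in microglia and one in neuronal RNA in their droplets cannot be told apart. The count of 1 became 0 without old rTg4510 replicate 4 or young WT replicate 3, and 5, 3, 3, 11 and 2 without old WT replicate 1, young WT replicate 1 or 2, old WT replicate 5 or young rTg4510 replicate 3. It rose to 40 without old rTg4510 replicate 3 and to 36 without young rTg4510 replicate 1. It was 0 with at least 50 cells, with only the groups compared, with the 16 animals and in microglia cluster 6 alone. It was 21 with a term for the ranges, 13 with no low-count filter, 2 above the lower quartile and 3 without mixed cells.

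Old P301L animals, which by their name carry the tau transgene without its activator, differed from old WT most often in microglia. There 63 genes were higher and 199 lower. The 2 microglia clusters were mixed differently: cluster 6 held 374 cells of P301L and 185 of WT animals, and cluster 12 held 153 and 219. Cluster 6 made up 11.3% of the cells of P301L and 3.47% of those of WT animals (exact permutation p = 0.018, unadjusted, tested after the clusters had been seen). With cluster 6 alone the comparison gave 226 calls. In cluster 12 alone, with fewer cells, 0 microglia genes were called, though the changes of Snap25, Syt1 and Rab3a stayed negative in all 18 alternatives (-3.79 to -2.31, -2.74 to -1.73 and -2.80 to -1.92). Transcripts of neurons were among those lower there. Neuron markers were lower at 8 of 11 members (10 adjusted over the list alone; median log2 change -2.36), synaptic vesicle genes at 10 of 16 (13 adjusted over the list alone) and postsynaptic genes at 8 of 12 (10 adjusted over the list alone), and each list's call was lost with an estimated correlation (adjusted p = 0.14 with an estimated correlation for each). Snap25, a vesicle fusion protein gene, stood at 718 ± 335 CPM (SD, n = 5) in WT and 115 ± 116 (n = 3) in P301L microglia (-2.73 ± 0.56, SE, adjusted p = 0.0047), and Syt1, a calcium sensor of release, at 680 ± 214 and 133 ± 56.7 (-2.36 ± 0.45). The glutamate receptor gene Grin1 had 33 counts in WT and 0 in P301L microglia, at least 8.76-fold lower. Genes of astrocytes were also lower, 5 of 14 homeostatic astrocyte genes (9 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), such as the gap junction gene Gja1 (-2.50 ± 0.60).

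Genes of microglia themselves were higher in P301L. Since CPM are scaled to the total, this rise cannot be told apart from the lower counts of neuron and astrocyte genes in the same droplets. Complement genes rose at 4 of 8 members (6 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), with C1qa at 1.34 ± 0.36, and lysosomal genes at 6 of 29 (10 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), with Gusb at 1.27 ± 0.35. Homeostatic microglia genes rose at 2 of 20 (10 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation), and microglia markers at 4 of 9 (7 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). The transglutaminase gene Tgm2 (1.97 ± 0.40) and Tbc1d5 (2.09 ± 0.65) rose as well, the latter with its call lost in 10 of 15 alternatives. Lpl had 1 count in P301L against 20 in WT microglia, a ratio of 15.9 (95% counting interval 2.55 to 660), and its call was lost in 9 of 17 alternatives. In oligodendrocytes 4 genes were higher and 22 lower, the latter led by the interneuron genes Sst, with 1 count against 95 (ratio 58.6, interval 10.3 to 2340), and Gad2, with 1 against 45. The 3 interneuron markers there fell by a median of 4.58 (2 called, 3 adjusted over the list alone; adjusted p = 0.025 with an estimated correlation).

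The comparison of P301L with WT gave 295 calls in 7 classes, with 3967 pairs at an unadjusted p under 0.05. Excitatory neurons had 0 calls by edgeR, with 815 genes at an unadjusted p under 0.05. Endothelial cells (13.1% of P301L and 5.99% of WT cells), microglia (8.36 percentage points higher than 7.64%) and mural cells (5.16% and 2.41%) had higher shares and excitatory neurons (18.3% and 30.7%) and interneurons (1.65% and 4.32%) lower ones, each with an exact permutation p of 0.018, the smallest possible here, and an adjusted p of 0.043. The 2 groups come from different parts of the table, and P301L animals were 41 to 48 weeks old against 32 to 40 for WT, so genotype, part and age cannot be told apart here. The count fell to 47 and 54 without P301L replicate 1 or 2 and to 134 without old WT replicate 4. It was 116 with a term for the ranges, 160 above the lower quartile and 164 without mixed cells. It was 171 with at least 50 cells, 33 with microglia cluster 12 alone and 465 with no low-count filter. P301L forms a range of its own, so the term sets it against the WT level of 1 range and cannot adjust this difference.

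Old rTta animals, which by their name carry the activator alone, differed from old WT in 217 pairs. Of these 112 were higher and 105 lower, with 76 calls each in microglia and oligodendrocytes. Microglia cluster 6 made up 6.73% of the cells of rTta and 3.47% of those of WT animals (exact permutation p = 0.018, unadjusted, tested after the clusters had been seen). With cluster 6 or 12 alone the comparison gave 197 and 155 calls. Several genes were nearly switched on or off. In oligodendrocytes Fcho1, an endocytosis gene (chromosome 8, 71708387 to 71725716), stood at 228 ± 30.4 CPM (SD, n = 5) in WT and 7.33 ± 8.57 (n = 3) in rTta (-4.99 ± 0.58, SE, adjusted p = 6.6e-07). Eya2 had 95 counts against 2, a ratio of 27.1 (95% counting interval 7.31 to 227), and Serpina3n fell by 2.91 ± 0.58. The phosphatase gene Dusp26 (2.36 ± 0.26), the cilia regulator gene Foxj1 (2.83 ± 0.66) and the securin gene Pttg1 (3.37 ± 0.43) rose. In rTta microglia Fcrls rose from 288 ± 158 to 2045 ± 96.1 CPM (2.84 ± 0.47), the cytokine receptor gene Crlf2 by 2.99 ± 0.66, and H2-DMa had 99 counts against 3 (ratio 35.6, interval 11.8 to 176). Complement genes rose at 4 of 8 members (7 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation), with C3ar1 at 1.72 ± 0.33. Neuron markers in these microglia had a median log2 change of -1.35, with 1 of 11 called (8 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation). In 9 genes the difference was called with 1 direction in 3 or more classes. There were 4065 pairs at an unadjusted p under 0.05. The part of the table and the genotype cannot be told apart in the design, and the count fell to 107 and 81 without rTta replicate 1 or 2 and rose to 343 with no low-count filter and 333 with only the groups compared.

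Against old rTta animals, which by their name share tTA, old rTg4510 animals gave 306 calls, 163 higher and 143 lower. In microglia 9 of 22 disease-associated genes rose (14 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation). Apoe rose from 2518 ± 352 CPM (SD, n = 3) to 48810 ± 19000 (n = 4), a log2 change of 4.28 ± 0.55 (SE, adjusted p = 2.6e-06), the receptor tyrosine kinase gene Axl by 4.32 ± 0.62 and Lpl by 3.61 ± 0.47. Of 20 homeostatic genes 6 fell (14 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), among them Slc2a5 (-3.24 ± 0.37), Olfml3 (-1.79 ± 0.38) and the purine receptor gene P2ry12 (-1.56 ± 0.36). Astrocyte markers in these microglia had a median log2 change of 1.53 (1 of 9 called, 7 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation). In astrocytes 7 of 15 cholesterol synthesis genes fell (15 adjusted over the list alone; adjusted p = 0.0017 with an estimated correlation), including Insig1 (-2.45 ± 0.35), Mvd (-1.99 ± 0.42) and Fdft1 (-1.41 ± 0.30). Reactive astrocyte genes rose at 3 of 12 members (8 adjusted over the list alone; adjusted p = 0.054 with an estimated correlation), with Serpina3n at 4.71 ± 0.76. Mapt and Prnp rose in excitatory neurons by 1.53 ± 0.18 and 1.37 ± 0.23. Here too genotype and part of the table go together, and the count fell to 154, 151 and 184 without rTta replicate 1, 2 or 3 and rose to 586 with only the groups compared. There were 3819 pairs at an unadjusted p under 0.05.

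Against old P301L animals, which by their name carry the tau transgene without its activator, old rTg4510 animals gave 428 calls. Of these 213 were higher and 215 lower, and 319 were in microglia. Of 22 disease-associated genes 13 rose (15 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), and 11 of 20 homeostatic genes fell (12 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation). Apoe rose by 3.33 ± 0.52 (SE, adjusted p = 0.00019), Axl by 3.85 ± 0.60, and Lpl had 566 counts against 1 (ratio 159, 95% counting interval 28.4 to 6290), while Slc2a5 fell by 3.15 ± 0.37 and Tmem119 by 1.63 ± 0.39. Neuron markers in microglia were higher at 6 of 11 members (8 adjusted over the list alone; median 1.82; adjusted p = 0.27 with an estimated correlation). Heat shock genes were lower at 4 of 11 (4 adjusted over the list alone; adjusted p = 0.41 with an estimated correlation), with the near-identical copies Hspa1a and Hspa1b, between which counts are uncertain, at -2.88 ± 0.69 and -3.31 ± 0.95. The call of Hspa1b was lost in 11 of 17 alternatives. In excitatory neurons, with 85 calls, Mapt rose by 1.69 ± 0.19 and Car4 by 2.04 ± 0.37, and the mossy fibre gene C1ql2 fell by 2.19 ± 0.44. Oxidative phosphorylation genes were lower there at 3 of 46 members (5 adjusted over the list alone, adjusted p = 0.50 with an estimated correlation). The mix of clusters in this class differed, with cluster 13 holding 289 of 1225 excitatory neurons in rTg4510 and 43 of 586 in P301L animals. C1ql2 was among the leading genes of another cluster, cluster 2. There were 4616 pairs at an unadjusted p under 0.05, and the groups come from different parts of the table and differ in age, 32 to 38 weeks for rTg4510 and 41 to 48 for P301L. The count fell to 58 and 137 without P301L replicate 1 or 2 and to 232 without old rTg4510 replicate 3. It was 694 with only the groups compared and 223 with microglia cluster 12 alone.

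Old against young WT animals show what differed with age without the transgene. Oligodendrocytes gave 172 of 176 calls, 84 higher and 88 lower. Cholesterol synthesis genes fell at 4 of 13 members (11 adjusted over the list alone; adjusted p = 0.019 with an estimated correlation). Hmgcs1, an early enzyme of the pathway (chromosome 13, 119690379 to 119708260), went from 710 ± 179 CPM (SD, n = 4) in young to 165 ± 73.6 (n = 5) in old animals (-2.03 ± 0.28, SE, adjusted p = 1.7e-05), and Cyp51 fell by 1.81. Myelin genes fell at 6 of 19 members (8 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), with the membrane proteolipid gene Mal at -1.68 ± 0.17, Tspan2 at -1.34 ± 0.17, Cldn11 at -1.17 ± 0.16 and Mog at -0.94 ± 0.19. The cytokine gene Il33 rose by 2.72 ± 0.33 and the ribonuclease gene Rnase4 by 3.93 ± 0.47. Markers of other cells were higher in the same droplets: 12 of 12 neuron markers had positive changes, with a median of 0.80 (2 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation). Of interneuron markers 1 of 3 rose and of excitatory neuron markers 1 of 6 (3 and 3 adjusted over the list alone; adjusted p = 0.15 and 0.22 with an estimated correlation). So did 3 of 13 homeostatic astrocyte genes (10 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), and the haemoglobin gene Beta-s by 5.11 ± 1.28, whose counts near-identical copies make uncertain. The call of Beta-s was lost in 10 of 18 alternatives. Markers of oligodendrocytes themselves fell at 2 of 8 members, or 6 adjusted over the list alone. Their median log2 change was -0.43 (camera adjusted p = 0.15 with an estimated correlation). Since CPM are scaled to the total, higher counts from other cells can lower oligodendrocyte genes, myelin genes among them. This was not separated from a change in the cells.

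The other calls of old against young WT animals were Sox2, Csrp1 and Id4 in excitatory neurons and Apoe in oligodendrocyte precursors, of which all but Sox2 are named after their values were seen. Sox2 and Id4 are genes of glia, and astrocyte markers in those excitatory neurons had a median log2 change of 1.60 (9 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Microglia and astrocytes had 0 calls by edgeR, with 353 and 410 genes at an unadjusted p under 0.05. There were 3068 such pairs in all. Each range of animal numbers holds 1 age, so age and range cannot be told apart. The count fell to 101 without young WT replicate 3 and to 111 with only the groups compared.

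Old P301L against old rTta animals was the comparison within 1 part of the table, added after the parts had been seen. The P301L animals were 41 to 48 weeks old and the rTta animals 33, so genotype and age cannot be told apart. The comparison gave 92 calls, 51 higher and 41 lower, 34 of them in oligodendrocytes and 23 in microglia. In oligodendrocytes Fcho1 stood at 333 ± 89.4 CPM (SD, n = 3) in P301L and 7.33 ± 8.57 (n = 3) in rTta (5.52 ± 0.59, SE, adjusted p = 2.1e-07), Eya2 had 62 counts against 2 (ratio 28.7, 95% counting interval 7.62 to 242), and Pttg1 fell by 3.05 ± 0.49. Sst had 1 count in P301L and 30 in rTta oligodendrocytes, and 1 of 3 interneuron markers fell (2 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). In microglia Qpct, an enzyme that cyclises glutamine at protein ends, rose by 3.16 ± 0.54, and Fcrls fell by 2.65 ± 0.54. The stress gene Gadd45b was lower by a log2 change of -2.63 ± 0.52. There were 2760 pairs at an unadjusted p under 0.05. Without P301L replicate 1, 2 or 3 the count was 52, 31 and 143, and without rTta replicate 1, 2 or 3 it was 40, 40 and 48. It was 334 with only the groups compared, 161 with a term for the ranges and 146 with no low-count filter. Both groups form ranges of their own, so the term cannot adjust their difference.

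**Figure D3:**
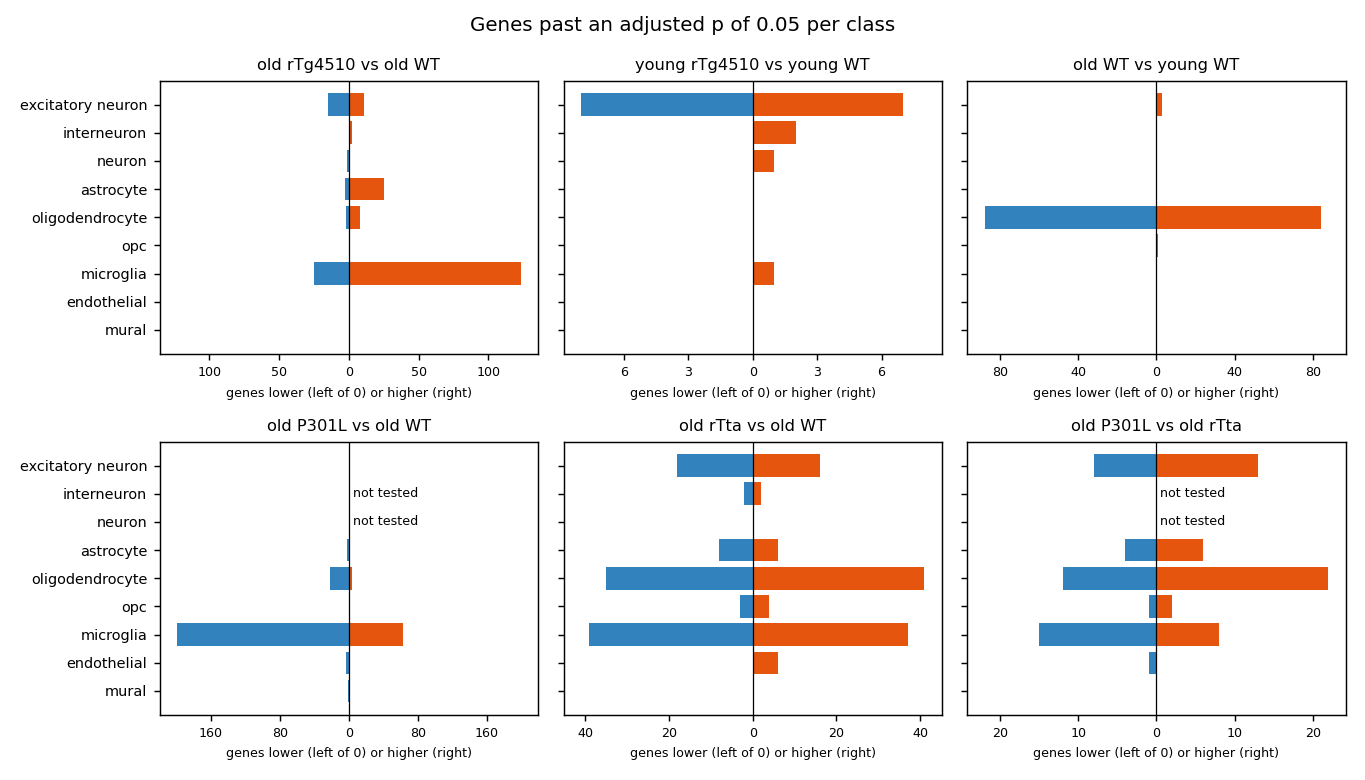
Genes past an adjusted p of 0.05 in each class, as bars to the right of 0 for genes higher and to the left for genes lower in the group named first; each panel is 1 comparison with its own scale. Microglia hold 148 of 215 calls between old rTg4510 and old WT animals, excitatory neurons 15 of 19 at the young age, and oligodendrocytes 172 of 176 between old and young WT.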

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

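Of the tests in this part, those of the microglia clusters and of astrocyte RNA, those of the 2 parts of the table, those of tTA, the splits of the first 3 comparisons and the count of young splits with the same balance of ranges were chosen only after the result was seen.

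Single animals stood far from the others of their group in 13 of 183 groups of values tested, where chance gives about 1 in 20. Choroid plexus cells made up 34.0% of old rTg4510 replicate 3 (0% in the other 3), 4.83% of old WT replicate 4 (0 to 0.601% in the others) and 11.3% of young WT replicate 3 (0 to 0.376%). The same old rTg4510 replicate 3 had 3.13% endothelial cells (6.08 to 6.40% in the others), 1.81% fibroblasts (0.188 to 0.386%) and 197.8 CPM of Aldh1a1 in astrocytes (56.3 to 80.3). In microglia, old WT replicate 4 had 486.4 CPM of Cd63 (121 to 223) and 25.2 CPM of H2-DMa (0 in the others), old rTg4510 replicate 2 had 1459 CPM of Cd74 (304 to 474), replicate 4 had 403.4 CPM of Gusb (266 to 288.5), and replicate 1 had 30.4 CPM of Wdr60 (46.3 to 48.8). Npy2r in excitatory neurons was at 9.84 CPM in old rTg4510 replicate 1 (16.2 to 17.5), and Ppp3r1 in astrocytes at 224.9 CPM in young WT replicate 3 (151 to 154).

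The difference between rTg4510 and WT microglia changed with age for Sepw1, by the interaction test (log2 -2.39, edgeR adjusted p = 0.023). Sepw1 was among the leading genes of excitatory cluster 4, so a change in microglia and one in neuronal RNA in their droplets cannot be told apart. Neuron markers in those microglia droplets also shifted, with a median log2 change of -0.54 between old and 0.96 between young rTg4510 and WT animals. Among genes left out of the main fits of all comparisons, 270 were at 0 in all 6 P301L and rTta animals and counted in each of the other 16, and 801 showed the opposite.

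The first pattern is the rise of disease-associated genes in microglia of old rTg4510 animals. A different mix of the 2 microglia clusters is argued against as the whole cause, since the lower of the 2 medians of the list within 1 cluster was still a log2 change of 1.21. RNA from astrocytes in the microglia droplets is argued against too, since the median change of astrocyte markers there was 0.0401. Tau pathology may lie behind the rise, which no test here separates from other differences between the genotypes.

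The second pattern is the lower level of neuronal transcripts in microglia and oligodendrocytes of old P301L animals. RNA from neurons in droplets of other cells may explain it, since neuron markers were lower in each of the 4 other classes examined, with a median log2 change of -1.51 in astrocytes, -1.21 in oligodendrocyte precursors, -0.99 in mural cells and -0.90 in endothelial cells, and excitatory neurons were a smaller share of the cells. An effect of the 2 parts of the table cannot be told apart from it: within 1 part, P301L against rTta microglia gave a median of -0.81, and the part, the genotype and an age of 41 to 48 weeks go together against WT. No biological explanation was tested.

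The third pattern is a set of 9 genes that differ between old rTta and old WT animals alike in 3 or more classes: Rpl3, Rps2, Rps18 and Pttg1 higher, and Scg5, Gabra2, Hddc3, Wdfy1 and Wdr60 lower. The parts of the table are argued against as the whole cause for the set, since P301L, of the same part, gave a median change of 1.14 against 3.68 in rTta. This median does not settle it for Scg5 and Gabra2. Over all cells each P301L animal lay below every old WT animal for both genes. Scg5 averaged 357.8 CPM in P301L, 742.9 in old WT and 225.7 in rTta, and Gabra2 129.4, 244.7 and 75.2. The tTA transgene is argued against for the 8 genes other than Wdr60, whose median change in rTg4510, which carries tTA, was -0.0381 against 3.73, while for Wdr60 it may hold, at 0.97 against 1.78. Inherited variants of the breeding line cannot be told apart from other causes that reach all classes of an animal: 100% of the 27 uncalled pairs of the 9 genes had the same sign, but in the animals in which the genes had been picked for such agreement. Counts of Rpl3, Rps2 and Rps18 are uncertain because of near-identical copies in the genome. P301L replicate 3 stood between the groups, with 71.9 CPM of Rpl3 over all cells against 233 in rTta and 4.49 in WT. For Scg5 (255.9 CPM, 203.3 to 256.8 in rTta) it stood within the rTta animals, and for Gabra2 (63.6, 69.5 to 85.1) below them. It stood with the other P301L animals for Hddc3 and Wdfy1.

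Other splits of the same animals were fitted for each comparison. For old rTg4510 against old WT, 3 of 50 splits gave as many calls (215 in the real one, 295 in the highest other). Chance could therefore not be excluded, and the split by ranges of animal numbers gave 1 call. The splits with 295 and 221 calls each kept old rTg4510 replicates 1, 2 and 4 together and put replicate 3 on the other side. The split with 295 calls also put old WT replicate 5 with replicates 1, 2 and 4, and that with 221 calls put old WT replicates 3 and 5 there. In the real split, with old rTg4510 replicate 3 left out, the count was 280. For young rTg4510 against young WT, 6 of 35 splits gave as many calls (19 and 738), so chance could not be excluded. The highest was the split of young WT replicates 1 and 2 and young rTg4510 replicate 1 from the rest, which follows the 2 ranges of animal numbers, and with a term for the ranges the count was 21. Among the 18 splits with the ranges balanced as in the real one, 1 gave as many calls, the real one, and the highest other gave 2, but 18 are too few for a share under 0.05. The count of 738 was many times the real one, which points to a structure of the samples. For the interaction, 33 of 50 did (1 and 223), and for old against young WT 3 of 50 (176 and 856), so chance could not be excluded for either, and the highest counts again point to a structure of the samples. Only the real split gave that many calls for P301L against WT (1 of 50, 295 and 98) and rTta against WT (1 of 50, 217 and 49). The same held for rTg4510 against rTta (1 of 35, 306 and 105) and rTg4510 against P301L (1 of 35, 428 and 106). These shares lie under 0.05 but were not adjusted over the comparisons. They concern groupings of these animals, not effects of the parts. For P301L against rTta the 10 splits are too few for a share under 0.05 (1 of 10; 92 and 0).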

How the results depend on the processing

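Removal of mixed cells, single clusters and the fit of 16 animals were alternatives chosen only after the data were seen. No called named gene or list turned its direction in the alternatives run, but 1 of the 215 calls between old rTg4510 and old WT had the opposite sign in microglia cluster 6 alone and 1 in excitatory cluster 2 alone, and uncalled differences in shares changed sign below. Of 215 calls between old rTg4510 and old WT, 190 were still called with RLE factors, 189 with DESeq2, 210 with a term for the ranges of animal numbers, 165 of 207 in cells above the lower quartile of counts and 139 of 202 with only the groups compared. Among called named genes in all comparisons, 241 stayed past the threshold with RLE factors and 7 did not, and with 1 animal left out 1357 stayed and 551 did not. No paired analysis was possible by replicate number because replicate numbers follow the order of the accessions and pair no animals. By age, old rTg4510 replicate 3 and old WT replicate 4 were both 35 weeks old. Old rTg4510 replicate 4 and old WT replicate 5 were both 32. The other old rTg4510 animals, of 38 and 37 weeks, shared no age with an old WT animal. A match by age was not tested, and the other splits of the old animals were not drawn to keep it. At the observed counts and numbers of animals, a log2 change of 1 was called for 28.0% to 66.3% of changed genes in simulated data. Those data held no variation shared among the genes of an animal. The cause of the shifts below was not tested.

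With no low-count filter the counts were 336 (old rTg4510 against old WT), 51 (young rTg4510 against young WT), 13 (interaction), 465 (P301L against WT), 343 (rTta against WT) and 146 (P301L against rTta). With DESeq2 they were 42 for the young animals and 19 for the interaction. With only the groups compared they were 0 (interaction), 333 (rTta against WT), 586 (rTg4510 against rTta), 694 (rTg4510 against P301L), 111 (old against young WT) and 334 (P301L against rTta). The term for ranges gave 21 (interaction), 116 (P301L against WT) and 161 (P301L against rTta); at least 50 cells gave 0 (interaction) and 171 (P301L against WT); the lower quartile gave 2 and 160, and removal of mixed cells 3 and 164. P301L and rTta form ranges of their own, so the term cannot adjust their differences. The interaction gave 0 with 16 animals and 0 with microglia cluster 6 alone. Microglia cluster 12 alone gave 109 (old rTg4510 against WT), 33 (P301L against WT) and 223 (rTg4510 against P301L), and excitatory cluster 2 alone gave 42 for the young animals.

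Within classes of old rTg4510 against old WT, no low-count filter gave 60 in astrocytes, 5 in endothelial cells, 5 in mural cells, 0 in the neurons of cluster 15, 23 in oligodendrocytes and 6 in their precursors. The term for ranges gave 43 in astrocytes, 46 in excitatory neurons, 1 in mural cells, 2 in cluster 15 neurons and 20 in oligodendrocytes. DESeq2 gave 48 in excitatory neurons and 19 in oligodendrocytes, and only the groups compared gave 96 in microglia, 3 in cluster 15 neurons and 4 in oligodendrocytes. The lower quartile gave 16 in astrocytes, at least 50 cells 15 in precursors, removal of mixed cells 1 in mural cells, cluster 2 alone 91 in excitatory neurons and cluster 12 alone 42 in microglia. Of 219 list and class pairs, 88 were called with the preset correlation, 20 with an estimated one and 28 with fry.

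With 1 animal left out, counts ran from 106 to 280 (old rTg4510 against WT; 125 without WT 1, 106 and 129 without rTg4510 1 or 2), 9 to 42 (young; 11, 9 and 34 without WT 1, 2 or 4, 42, 12 and 12 without rTg4510 1, 2 or 3), 0 to 40 (interaction; 5 and 11 without old WT 1 or 5, 3, 3 and 0 without young WT 1, 2 or 3, 36 and 2 without young rTg4510 1 or 3, 40 and 0 without old rTg4510 3 or 4), 47 to 395 (P301L against WT; 134 without WT 4, 47 and 54 without P301L 1 or 2), 81 to 272 (rTta against WT; 107 and 81 without rTta 1 or 2), 151 to 329 (rTg4510 against rTta; 154, 151 and 184 without rTta 1, 2 or 3), 58 to 480 (rTg4510 against P301L; 232 without rTg4510 3, 58 and 137 without P301L 1 or 2), 101 to 207 (old against young WT; 101 without young WT 3) and 31 to 143 (P301L against rTta; 52, 31 and 143 without P301L 1, 2 or 3, 40, 40 and 48 without rTta 1, 2 or 3).

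Within classes the ranges were 4 to 23 in astrocytes (7, 18, 12 and 17 without old WT 1, 3, 4 or 5, 8 and 4 without rTg4510 1 or 3), 0 to 0 in endothelial cells, 12 to 35 in excitatory neurons (14 and 16 without WT 1 or 5, 12, 12 and 17 without rTg4510 1, 2 or 4), 1 to 2 in interneurons (1 without WT 3, WT 5 or rTg4510 4), 83 to 229 in microglia (89 without WT 1, 83, 86 and 229 without rTg4510 1, 2 or 3), 0 to 3 in mural cells (3 and 2 without WT 1 or 5), 0 to 1 in cluster 15 neurons (0 without WT 3, WT 4, rTg4510 1 or rTg4510 4), 1 to 26 in oligodendrocytes (5 and 4 without WT 2 or 4, 1, 5 and 26 without rTg4510 1, 2 or 3), 0 to 7 in precursors (7 without WT 5, 1 without rTg4510 4) and 4 to 6 for transgene genes. Differences in shares ran, in percentage points, from -1.58 to 3.04 (astrocytes), -1.09 to 10.2 (choroid plexus), -1.10 to 0.21 (endothelial), -9.81 to -6.78 (excitatory), -0.681 to 0.023 (fibroblasts), -0.339 to 0.595 (interneurons), 6.63 to 12.2 (microglia), -0.563 to 0.018 (mural), -0.182 to 0.904 (cluster 15 neurons), -7.99 to -2.81 (oligodendrocytes), -2.48 to -0.607 (precursors) and -2.02 to 1.053 (unnamed), and 0 to 0 shares passed.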

Other observations

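The values of the clusters here were looked at only after the clusters had been seen, and the tests among them were chosen then.

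Among cells left unnamed, a cluster led by Gpr17, Enpp6, Fyn and Bmp4, genes of newly forming oligodendrocytes, made up 2.03% of cells in young WT and 2.56% in young rTg4510 animals. It made up 0.369% in old WT, 0.694% in old rTg4510, 0.667% in P301L and 0.50% in rTta animals. A cluster led by Cenpf, Sox11, Nusap1 and Neurod1, genes of dividing cells and immature neurons, made up 1.07% and 1.52% in the young groups, 0.156% in old WT, 0.201% in old rTg4510, 0.111% in P301L and 0.236% in rTta animals. Old and young WT animals differed for both by the exact permutation test (p = 0.0079 for each, unadjusted, the smallest 5 against 4 animals can give). A cluster led by Cd74, Cd52 and Ptprc, genes of immune cells, held 25 cells of old rTg4510, 9 of old WT, 6 of P301L, 10 of rTta, 0 of young WT and 1 of young rTg4510 animals, and was not tested.

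Within groups, the animals varied along 1 axis that held 26.9% of the variation of 4429 genes in excitatory neurons, 21.2% of 4071 in astrocytes and 20.5% of 3798 in oligodendrocytes. In excitatory neurons Kcnq1ot1, Rpl38, Erdr1 and Leng8 lay at one end and Enpp2, Beta-s and Mbp at the other. In all 3 classes young WT replicates 1 and 2 and young rTg4510 replicate 1 had positive positions and the other 4 young animals negative ones. This is the split by ranges of animal numbers that gave 738 calls. Old animals of 1 range lay on both sides of 0.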
